A study of Mus musculus with 16 samples.

How the data were processed

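RNA abundance was measured on 16 Affymetrix Mouse Genome arrays, 4 for each of 4 groups. B1a cells of the peritoneal cavity and CD43-negative splenic B cells (Bs) came from C57BL/6 (B6) mice and from congenic B6.Sle2c1 (Sle2c1) mice, all 5 months old. Per the labels, peritoneal macrophages were depleted by adherence during 2 h of culture in 10% serum, Thy1.2 and CD3ε antibodies served for negative selection and a CD5 antibody for positive selection. The labels put the B1a preparations at 80% B220int CD5+ cells and the splenic ones above 90% B220hi cells. RNA was amplified and labelled with biotin (NuGEN Ovation). No label gives the sex of the mice, a processing day, or what the replicate numbers mean.

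The authors deposited 1 table of 45101 probe sets, of which 64 are array controls, and no count or depth underlies its values, so that the number of arrays limits the precision. The unit of the deposited values is a score. It behaves like a log signal shifted and scaled array by array, and the sources used here do not give its log base, centring or scaling. The deposited score does not look like log2, because the means of the hybridisation controls bioB and cre lay only 0.688 to 1.70 units apart. Differences are therefore given in units of this score and never turned into fold changes, although log2 values had been assumed when the comparisons were planned. Each array had its own lowest value, between -7.72 and -4.99, shared by 22.8% to 35.6% of its probe sets (median 26.7%). Such values carry no level. All values below 0.495, the median over arrays of the 40th percentile, were raised to 0.495, called the floor below. The floor was chosen after the table had been seen and before any test. Where every array of a group lay at the floor, the difference from another group is a lower bound.

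Probe sets above their array's 40th percentile on at least 4 of the 16 arrays were used (35032 probe sets). Gene names came from the platform annotation, with 34958 probe sets assigned to 1 gene, 932 to several and 9211 to none. Symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCm38.p6, which matched 99.42% of the probe sets with 1 gene. The deposited data name no genome build, so no coordinates are given, and the table served for names and gene order alone. The probe set with the highest mean stood for a gene. This left 22727 features, of which 15129 were named genes and 7598 were probe sets without a single name.

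The 4 group means were fitted in 1 model over the 16 arrays with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). Moderated tests were two-sided, with Benjamini-Hochberg adjustment over all 22727 features and a threshold of adjusted p under 0.05. A feature that passed is called higher or lower. The comparisons were Sle2c1 against B6 in B1a cells and in Bs cells, the difference of these strain effects (interaction), and B1a against Bs cells in each strain. Cdkn2c was also tested by an exact two-sided permutation test of 4 against 4 arrays. The 50 named genes on either side of Cdkn2c in gene order were compared with all others by Fisher's exact test.

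Gene lists from textbook knowledge, 33 in number with 529 genes (455 measured), were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 33 lists within a comparison. They cover cell cycle regulators, S phase, mitosis, B1a, follicular, marginal zone, germinal centre and plasma cell genes, ER stress, type I interferon, MHC class II, B cell receptor, immediate early, heat shock, apoptosis, p53, homing, Toll-like receptor, glycolysis, lipid, ribosomal, oxidative phosphorylation and sex-linked genes. The other 10 hold markers of T cells, macrophages, NK cells, neutrophils, mast cells, eosinophils, dendritic cells, erythroid cells, mesothelium and stroma, and platelets. Members were counted over all features and adjusted over the list alone. Each camera test was repeated with an estimated correlation.

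The genes named are Cdkn2c, the 12 higher and 12 lower genes with the largest differences among those past the threshold whose groups did not overlap (5 and 5 for the interaction), up to 4 members of each list with the smallest adjusted p, and genes near Cdkn2c that passed. Predicted genes and clones were counted and not named unless among the 3 largest. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were other filters, other ways from probe sets to genes, other scalings, other forms of the test, other thresholds and leaving out each array. Replicate number as a block was planned as well. Other floors, with and without each gene's probe set held, leaving groups at the floor out of the estimated spread, blocks within a cell type, leaving out 3 arrays in doubt (Sle2c1_B1a 4, B6_Bs 3 and Sle2c1_Bs 3), and testing only genes above the floor were added later. B6_Bs 1 was not among these 3, although it lay at -11.5 on the first principal component, apart from the other Bs arrays.

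Arrays of equal number were treated as paired if their residual profiles correlated above 0.1 across genes for each number. This held for the strain comparison in Bs (0.112 to 0.621) and for no other comparison, so blocked values stand beside that result. On data with simulated changes, 60% of 0.5-unit changes and 75% of 1-unit changes among 22727 features were recovered, with 8 false calls among 143. The list test found 1 of 1 simulated list changed by 0.3 units and called 0 of 20 lists left as they were. Genes were simulated independently of each other, so that this says nothing on false calls of lists whose genes correlate. Single changes were placed only in features with a mean above 1 unit, and recovery nearer to the floor was not measured.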

Results

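Transcript levels were measured in B1a cells of the peritoneal cavity and in splenic B cells (Bs) from B6 mice and from B6.Sle2c1 mice, on 4 arrays per group. The congenic Sle2c1 mice carry a segment of the lupus-prone NZM2410 strain that holds Cdkn2c. Median values of the 16 arrays ranged from 0.68 to 1.12 units of the deposited score (median 0.885). Correlations between arrays were 0.799 to 0.973 within groups and 0.708 to 0.981 between groups. The first principal component (48.8% of the variance) placed all 8 B1a arrays on its negative side and 7 of the 8 Bs arrays on its positive side. The exception, B6_Bs 1, lay at -11.5. Sle2c1_B1a 4 (-2.40, and -55.6 on the second component) and B6_Bs 3 (61.3) also lay apart from their groups. Replicates of a group differed less at high levels. For levels between 2 and 3 units the median replicate SD was 0.0591 in B6_B1a, 0.0763 in Sle2c1_B1a, 0.0922 in B6_Bs and 0.0741 in Sle2c1_Bs.

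Cdkn2c, which encodes the Cdk4/6 inhibitor p18INK4c and is the gene named in the title of the series, was lower in Sle2c1 than in B6 cells of both types. Its single probe set read 1.21 ± 0.132 units (SD, n = 4) in B6_B1a and 0.613 ± 0.183 in Sle2c1_B1a, a difference of -0.60 (SE 0.102, adjusted p = 0.00392). In Bs cells it read 1.42 ± 0.172 in B6 and 0.521 ± 0.0525 in Sle2c1, a difference of -0.89 (adjusted p = 0.00114). Every B6 array lay above every Sle2c1 array of the same cell type, and the exact permutation p was 0.0286 in each, the smallest that 70 arrangements can give. With the Bs arrays paired by replicate number, 4 of 4 pairs were lower in Sle2c1 and the exact permutation p was 0.125, the smallest that 4 pairs can give. With the block in a fit of the 8 Bs arrays alone the call of Cdkn2c ended (adjusted p = 0.242). Signal stayed above the floor on 2 of 4 Sle2c1_B1a arrays and 1 of 4 Sle2c1_Bs arrays, and with a floor at 1 unit Cdkn2c passed in neither cell type (adjusted p = 0.185 and 0.0602). Over the alternatives run, apart from single arrays left out, its adjusted p ranged from 0.00327 to 0.407 in B1a and from 2.01e-05 to 1 in Bs, the highest values with no floor. The strain differences of Cdkn2c in the 2 cell types differed by 0.29 (SE 0.145, adjusted p = 0.71). Cdkn2c did not pass the test between cell types, with B1a minus Bs at -0.20 in B6 (adjusted p = 0.177, exact permutation p = 0.114) and 0.09 in Sle2c1 (adjusted p = 0.541, exact permutation p = 0.714).

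**Figure D1:**
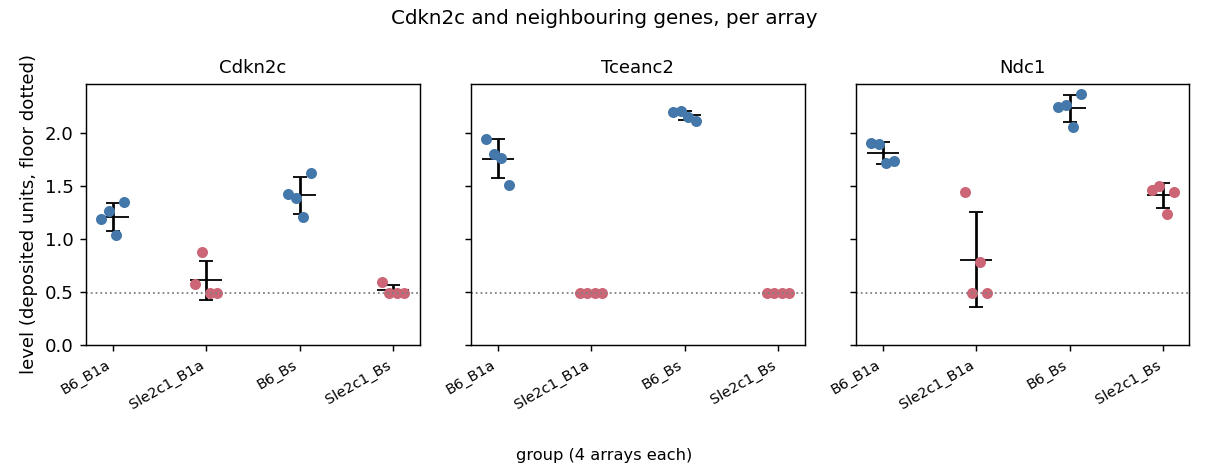
Level of Cdkn2c, Tceanc2 and Ndc1 on each array (y axis, units of the deposited score) by group (x axis), with each group's mean and SD (n = 4) and the floor of 0.495 as a dotted line. Tceanc2 lay at the floor on all 8 Sle2c1 arrays and averaged 1.76 in B6_B1a and 2.17 in B6_Bs.

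Because the congenic segment surrounds Cdkn2c, its neighbours in gene order were examined separately. Tceanc2, 35 genes away, lay at the floor on all 8 Sle2c1 arrays, against 1.76 ± 0.184 units in B6_B1a and 2.17 ± 0.0411 in B6_Bs. Its differences of -1.27 in B1a (adjusted p = 2.57e-07) and -1.68 in Bs (adjusted p = 3.95e-08) are therefore lower bounds of the size of the difference in signal. Here, as for Cdkn2c and the neighbours below, whether the transcript or only the signal of the probe set differed was not tested. Ndc1, which encodes a nucleoporin, fell by 1.01 in B1a (adjusted p = 0.00303), although 0 of its 2 other probe sets differed in that direction. In Bs Ndc1 differed by -0.82 without passing (adjusted p = 0.104). Yipf1 fell by 0.39 in B1a (adjusted p = 0.0481), a call that ended without any 1 of 7 of the 8 arrays (adjusted p 0.0576 to 0.122), and differed by -0.09 in Bs (adjusted p = 1). Among the 100 named genes nearest to Cdkn2c, 3 passed in B1a (3%, against 3.47% of the other 15028, Fisher's exact p = 1) and 1 in Bs (1% against 0.146%, Fisher's exact p = 0.142). Counting genes at an adjusted p under 0.10 in Bs, Fisher's exact p was 0.104, 0.02 and 0.00928 with 25, 50 and 100 genes on either side, and at 0.05 it was 1 with 25 and 0.264 with 100.

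In B1a cells, the comparison of strains asks how the Sle2c1 segment alters the population that expands in lupus-prone mice. Sle2c1_B1a arrays had lower signal of macrophage markers (camera adjusted p = 6.64e-13, and 0.285 with an estimated correlation), and higher signal of other features, of which 131 lay at the floor on all 4 B6_B1a arrays. The macrophage phosphatidylserine receptor Timd4 read 2.25 ± 0.549 units in B6_B1a and lay at the floor on all 4 Sle2c1_B1a arrays. The lipoprotein Apoe read 1.70 ± 0.177 in B6_B1a and was at the floor in Sle2c1_B1a. Angiogenin (Ang) went the other way, from 0.619 ± 0.248 to 2.21 ± 0.0796 units. Of 22727 features, 439 were higher and 329 lower in Sle2c1_B1a (255 and 271 of them named genes), with 3903 at an unadjusted p under 0.05. The majority of higher features did not hold after quantile normalization (457 higher, 469 lower), after median centring (444 and 466) or among features above the floor on all 8 arrays (19 and 31). The groups did not overlap for 8.38% of all features, where chance gives at most 2.86%, and less where many arrays are tied at the floor.

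The lower genes in Sle2c1_B1a with the largest differences included Timd4 (-1.75, adjusted p = 0.00137), the endothelin receptor Ednrb (-1.71, adjusted p = 0.00169), the complement component C1qb (-1.67, adjusted p = 0.00157), Ecm1 (-1.26, adjusted p = 7.09e-05) and Apoe (-1.21, adjusted p = 2.97e-06). Each of these is a lower bound of the size because all Sle2c1_B1a arrays lay at the floor. Serpinb2, the plasminogen activator inhibitor 2, fell by 1.59 (adjusted p = 0.0051). Lubricin (Prg4) fell by 1.55 from 2.39 units (adjusted p = 0.00341), fibronectin (Fn1) fell by 1.36 (adjusted p = 0.00871) and platelet factor 4 (Pf4) fell by 1.34 (adjusted p = 0.00444). The neutrophil chemokine Cxcl1 fell by 1.35 from 2.80 units (adjusted p = 0.0146), and the aggrecanase Adamts4 fell by 1.25 (adjusted p = 1.5e-05). Tceanc2 completes these 12. Among the higher genes were Ang (1.59), keratin 13 (Krt13, 1.47), Pxt1 (1.47), the olfactory receptor Olfr480 (1.42), the transcription factor Sox11 (1.41) and phospholipase D1 (Pld1, 1.41). Others were the acetylcholine receptor chaperone Ric3 (1.40), Sall3 (at least 1.36), the glycogen-targeting phosphatase subunit Ppp1r3g (1.34), Limch1 (at least 1.33), the ETS factor Elf5 (1.29) and neuroglobin (Ngb, 1.29). Their adjusted p ran from 2.96e-09 to 0.00143, and their B6_B1a means were all under 0.81 units. The other probe sets of Sox11 (3 of 3), Pld1 (2 of 2) and Ric3 (2 of 2) were higher too, that of Sall3 (0 of 1) was not. Each of these 24 calls held without any 1 of the 8 arrays, 18 held with only the 8 arrays compared, 22 with floored groups out of the spread and 5 with no floor.

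Macrophage markers were lower as a group in Sle2c1_B1a. Over all features 7 of 16 were lower and none higher, 11 were lower when adjusted over the list alone, the median difference was -0.775 and camera gave an adjusted p of 6.64e-13 (adjusted p = 0.285 with an estimated correlation). Besides Timd4, C1qb, Prg4, Fn1 and Apoe, the growth factor receptor Csf1r was lower (-0.83, a lower bound of the size, adjusted p = 0.00323). The list averaged 1.81 ± 0.395 units over the B6_B1a arrays, which ranged from 1.32 to 2.28, and 1.04 ± 0.0289 over the Sle2c1_B1a arrays. Immediate early and activation genes had a median difference of -0.167 (adjusted p = 7.67e-05, adjusted p = 0.285 with an estimated correlation), with 1 of 23 lower, Ier2 (-0.74, adjusted p = 0.0059), and 7 lower and 1 higher when adjusted over the list alone. Of 20 cell cycle regulators of the Cdk4/6 and Cdk2 pathways, Cdkn2c and the transcription factor E2f2 (-0.38, adjusted p = 0.042) were lower, 6 were lower adjusted over the list alone, and the median was -0.19 (adjusted p = 0.00212, adjusted p = 0.285 with an estimated correlation). Cyclin D2 (Ccnd2) differed by -0.28 and p21 (Cdkn1a) by -0.53 without passing (adjusted p = 0.07 and 0.0916). Ribosomal protein genes had a median of -0.104 with 0 of 24 past the test (limma; adjusted p of the list = 0.000155, 0.377 with an estimated correlation). Of 13 plasma cell genes, the antibody joining chain Jchain fell by 0.59 from 2.53 units (adjusted p = 0.00797) and the receptor Slamf7 rose by 0.49 (adjusted p = 0.0157). The list's median was -0.103 (adjusted p = 0.0245, adjusted p = 0.285 with an estimated correlation), with 1 higher and 3 lower adjusted over the list alone.

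The other 28 lists did not pass between the strains in B1a. Their adjusted p was 0.0741 for mitosis, 0.114 for S phase, 0.164 for B1a cell genes, 0.0918 for follicular, 0.171 for marginal zone and 0.854 for germinal centre B cell genes. It was 0.15 for ER stress, 0.846 for type I interferon, 0.114 each for MHC class II, B cell receptor and heat shock genes, 0.218 for apoptosis, 0.375 for p53 targets and 0.569 for oxidative phosphorylation. Single members passed in homing (the integrin Itga4, -0.28, list adjusted p = 0.15), Toll-like receptor signalling (the RNA sensor Tlr7, 0.34, list adjusted p = 0.218), glycolysis (Pfkl, -0.68, list adjusted p = 0.125) and lipid uptake (lipoprotein lipase Lpl, -1.12 as a lower bound of the size, list adjusted p = 0.0674). Among markers of other cells, the list adjusted p was 0.0674 for T cells (Cd3g, -0.87, adjusted p = 0.0146), 0.826 for NK cells, 0.569 for neutrophils, 0.0883 for mast cells, 0.593 for dendritic cells, 0.401 for erythroid cells, 0.758 for mesothelium and stroma and 0.15 for platelets (Pf4). Eosinophil markers split, with Epx (-0.66) and Alox15 (-1.07) lower and Ccr3 higher by at least 0.96 (list adjusted p = 0.592), and sex-linked genes gave 0.164 with Uty higher by at least 0.92. Uty is Y-linked, yet the Sle2c1_B1a arrays read Xist at 3.26 to 3.28 and the Y-linked Eif2s3y and Kdm5d at no more than 1.14 and 1.27. The rise of Uty signal need therefore not be one of its transcript. The median differed in sign from the mean for eosinophil markers and oxidative phosphorylation. The interleukin Il10, a product of B1a cells, read 2.81 ± 0.0469 units in B6_B1a and 2.65 ± 0.0966 in Sle2c1_B1a (-0.16, adjusted p = 0.128), and Cd5 differed by -0.33 (adjusted p = 0.291). The calls of E2f2, Tlr7 and Uty ended without any 1 of 7, 5 and 7 of the 8 arrays (adjusted p 0.0541 to 0.123, 0.0508 to 0.102 and 0.0668 to 0.103). That of Slamf7 ended without B6_B1a 3 (0.0554) and that of Alox15 without B6_B1a 1 (0.0512). With groups wholly at the floor left out of the spread, 258 features were higher and 196 lower. Among the 9715 features above the floor on all 8 arrays, 50 passed when adjusted among themselves.

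In splenic B cells, the same comparison asks what the segment alters in the main B cell population. Few genes passed, and the largest difference was the loss of Tceanc2 signal, with Cdkn2c second among the lower genes. Elf5 rose by 1.13 units from 0.67 ± 0.34 to 1.80 ± 0.188, Ang by 1.03 and Ric3 by 1.02. In all, 28 features were higher and 7 lower (19 and 5 named genes), with 778 at an unadjusted p under 0.05. The groups did not overlap for 2.34% of all features, where chance gives at most 2.86%. It gives less where many arrays are tied at the floor, so that this share is not shown to fall short of chance.

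The higher named genes in Sle2c1_Bs with the largest differences were Elf5 (adjusted p = 0.00715), Ang (adjusted p = 0.0135), Ric3 (adjusted p = 0.00403), Ppp1r3g (0.99, adjusted p = 0.000545), the parathyroid hormone receptor Pth1r (0.98, adjusted p = 0.0221) and Pxt1 (0.96, adjusted p = 0.00891). They were followed by the growth suppressor Ndn (at least 0.94, adjusted p = 0.0211), Zfp518b (at least 0.92, adjusted p = 0.005), the proteoglycan Spock1 (0.91, adjusted p = 0.00384), the retinol acyltransferase Lrat (0.82, adjusted p = 0.0327), Fam71b (0.79, adjusted p = 0.00496) and Dnaaf6 (0.79, adjusted p = 0.000542). Besides Tceanc2 and Cdkn2c, the lipid phosphatase Plpp2 fell by 0.58 from 1.15 to 0.566 units (adjusted p = 0.00891). Lrp12 (-0.57, adjusted p = 0.000542) and the apoptosis regulator Pawr (-0.52, adjusted p = 0.0224) were lower from means near 1 unit, both as lower bounds of the size. With groups at the floor left out of the spread, Lrp12, Pawr and Ndn no longer passed (adjusted p = 0.616, 0.146 and 1). Ang and Pxt1 did not pass without B6_Bs 2 (0.0725 and 0.0527). Lrat, Ndn, Pawr and Pth1r did not pass without any 1 of 7, 5, 5 and 5 of the 8 arrays (adjusted p 0.0575 to 0.155, 0.0725 to 0.0969, 0.0641 to 0.0989 and 0.0818 to 0.0989). Of these 17 calls, 14 held with trend and robust, 9 after median centring and 6 after quantile normalization. With only the 8 arrays compared 5 held, with a floor at 1 also 5, and with no floor 2.

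Mitotic genes had a median difference of -0.275 in Sle2c1_Bs (camera adjusted p = 2.19e-20), and this list alone among the 14 past the test also passed with an estimated correlation (adjusted p = 0.00994). With the replicate block within each cell type as well, it did not (adjusted p = 0.0927). None of its 31 members passed over all features in limma, and 9 were lower adjusted over the list alone. The list averaged 1.75 ± 0.0662 units in B6_Bs and 1.49 ± 0.03 in Sle2c1_Bs. Cyclin B2 (Ccnb2) differed by -0.87, the kinetochore gene Ndc80 by -0.41, topoisomerase Top2a by -0.36 and Cks2 by -0.33 (adjusted p = 0.376, 0.413, 0.519 and 0.0735). S phase genes had a median of -0.141 (adjusted p = 1.95e-11, adjusted p = 0.0625 with an estimated correlation) and cell cycle regulators one of -0.065 with Cdkn2c the single member past the test (0.000166, adjusted p = 0.13 with an estimated correlation). Germinal centre genes had a median of -0.283 (0.000192, adjusted p = 0.0762 with an estimated correlation), with 3 of 8 lower adjusted over the list alone. Lists of more general processes also passed at the preset correlation (adjusted p 6.72e-06 to 0.0147). They were type I interferon (median -0.0913), immediate early (-0.055), heat shock (-0.1), ER stress (-0.045), ribosomal (-0.03) and oxidative phosphorylation genes (-0.0275). With an estimated correlation their adjusted p was 0.174, 0.227, 0.0625, 0.186, 0.554 and 0.259. Markers of other cells moved with them. Macrophage markers had a median of -0.175 (adjusted p = 1.61e-07, adjusted p = 0.174 with an estimated correlation), neutrophil markers -0.316 (2.24e-05, adjusted p = 0.163 with an estimated correlation), erythroid markers -0.366 (0.000166, adjusted p = 0.106 with an estimated correlation) and NK cell markers -0.0437 (0.0101, adjusted p = 0.174 with an estimated correlation). All 14 lists past the test in Bs were lower and 0 were higher, so that the lower mitotic and S phase lists were not apart in direction. The other 19 lists did not pass (lowest adjusted p = 0.0792, glycolysis), and MHC class II, homing and platelet lists differed in sign between median, mean and test.

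Bs arrays of equal replicate number resembled each other, and with replicate number as a block 30 features passed, 25 with a block within each cell type, and 1 (Tceanc2, adjusted p = 0.0115) with the block in a fit of the 8 Bs arrays alone. Counts were 22 without B6_Bs 2 and 63 without B6_Bs 3, and quantile normalization gave 9 higher and 5 lower in place of 28 and 7. Among the 11892 features above the floor on all 8 Bs arrays, limma called 0 when adjusted among themselves, with 286 at an unadjusted p under 0.05.

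Some strain differences passed in both cell types. Of the features higher in Sle2c1, 18 passed in both, where 0.541 would by chance were the tests independent (Fisher's exact p = 1.09e-24). The tests are not independent, because they share the estimated spread of each feature, and the features are not independent of each other. The 18 rest on the Bs calls without the replicate block. With the block in the 8 Bs arrays alone the single feature that passed was the lower Tceanc2. The 18 include Ang, Elf5, Krt13, Pld1, Ppp1r3g, Pth1r, Pxt1, Ric3, Spock1, Zfp518b, Dnaaf6 and Vat1, with differences of 0.73 to 1.59 in B1a and 0.71 to 1.13 in Bs. Cdkn2c, Tceanc2 and a probe set without a gene name were lower in both (0.101 by chance on the same assumption, Fisher's exact p = 0.000101), and 0 features passed in opposite directions in the limma tests. Of the 701 features past the test in B1a with any difference in Bs, 522 (74.5%) had the same sign there, and the strain differences correlated across all genes with r = 0.414 (Spearman 0.360), where genes are not independent replicates.

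The interaction asks where the strain effect depends on the cell type, and it cannot part the cell type from what went with it. The labels give the 2 h of culture for the B1a preparations alone. The sex-linked Xist, Eif2s3y and Kdm5d and the Dap control also parted all B1a from all Bs arrays. The test passed for 98 features, and 1686 had an unadjusted p under 0.05. Of the 98, 60 had a more positive and 38 a more negative strain difference in B1a than in Bs (41 and 31 named genes). The largest positive interactions were of 1700073E17Rik (1.45), Olfr480 (1.42), Sall3 (1.36), Limch1 (1.32) and Tdpoz1 (1.24), which rose in Sle2c1_B1a and lay at or near the floor in both Bs groups (adjusted p 3.52e-07 to 5.82e-05). The largest negative ones were of Timd4 (-1.92, adjusted p = 0.0358), which read 1.07 in B6_Bs and 1.24 in Sle2c1_Bs, Adamts4 (-1.45, adjusted p = 0.000533), the fatty acid amide hydrolase Faah (-1.30, adjusted p = 0.0248), the scavenging chemokine receptor Ackr3 (-1.30, adjusted p = 0.000631) and Lpl (-1.30, adjusted p = 0.0177). Ackr3 lost its signal in Sle2c1_B1a, from 1.39 ± 0.249 to the floor, and read 1.94 ± 0.116 in B6_Bs and 2.35 ± 0.0846 in Sle2c1_Bs. For 9 of these 10 genes a group lay wholly at the floor, so that the size rests on where the floor was set, and for Faah the group means ran from 0.924 to 1.79.

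Macrophage markers led the lists here too, with 2 of 16 lower (6 adjusted over the list alone), a median of -0.567 and an adjusted p of 4.2e-06 (adjusted p = 0.443 with an estimated correlation). Mitosis (median 0.203, adjusted p = 0.00521), neutrophil markers (0.364, 0.0089) and germinal centre genes (0.347, 0.0454) had a more positive strain difference in B1a than in Bs, as did type I interferon genes (0.174, 0.0211). Follicular B cell genes (-0.185), immediate early genes (-0.101) and ribosomal genes (-0.0675) had the opposite sign (each adjusted p = 0.036). With an estimated correlation the adjusted p was 0.566 for ribosomal genes, 0.464 for type I interferon genes and 0.443 for mitosis, neutrophil, germinal centre, follicular and immediate early genes. The remaining 25 lists did not pass at the preset correlation (lowest adjusted p = 0.0677), and apoptosis and eosinophil lists differed in sign between median and mean. With groups at the floor left out of the spread 23 features passed, among them Limch1, Olfr480, 1700073E17Rik, Adamts4 and Ackr3 and not Sall3, Tdpoz1, Timd4, Faah or Lpl (adjusted p 0.0563 to 0.201). Counts were 48, 52, 52, 54 and 56 without B6_Bs 4, B6_Bs 2, Sle2c1_Bs 1, 2 and 3, 65 without B6_B1a 3 and 183 without Sle2c1_B1a 1. The calls of Timd4, Faah and Lpl ended without any 1 of 10, 7 and 2 of the 16 arrays (adjusted p 0.0543 to 0.0938, 0.0512 to 0.0681 and 0.0506 to 0.0527).

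B1a and Bs cells of B6 mice were compared as the reference difference between the populations. The labels give 2 h of culture in 10% serum for the B1a preparations alone, so that this step and the cell type cannot be told apart. B1a cells had high transcripts of Il10 (2.81 ± 0.0469 units against the floor on all 4 Bs arrays, adjusted p = 8.76e-13), the chemokine Cxcl2 (3.46 against 0.545, difference 2.92) and the B1a cell genes Plscr1, Zbtb32 and Ahr. Bs cells had high transcripts of complement receptor 2 (Cr2, 3.32 ± 0.0668 against 1.23 ± 0.146, adjusted p = 1.08e-07) and the IgE receptor CD23 (Fcer2a, 2.68 against 0.79). The B1a arrays also carried Xist (3.28 to 3.34 in B6_B1a, at most 1.12 on any Bs array), and the Bs arrays the Y-linked Eif2s3y (3.12 to 3.35) and Kdm5d (2.77 to 2.95), which stayed at or below 1.27 in B1a cells. These 3 genes parted all B1a from all Bs arrays in both strains, and the labels give no sex. The Y-linked Uty did not part them, with 0.495 to 1.78 in Sle2c1_B1a against 0.83 to 1.68 in Bs. As far as Xist, Eif2s3y and Kdm5d tell it, the sex of the mice went with the cell type and cannot be told apart from it. In B6, 2050 features were higher and 2783 lower in B1a cells (1702 and 1667 named genes), with 7925 at an unadjusted p under 0.05. The groups did not overlap for 22.4% of features, where chance gives at most 2.86%.

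Besides Cxcl2, Xist and Il10, the largest higher differences were of Snd1 (at least 2.75), Usp50 (2.56), the Wnt receptor Fzd6 (at least 2.52), Serpinb2 (at least 2.48), Efcab1 (2.46) and Syne2 (2.40). Next came the endotoxin receptor Cd14 (2.37), casein kinase Csnk1e (at least 2.34) and the acute phase gene Saa3 (2.32). The largest lower ones were of the ribosomal gene Rps27 (-2.85), Eif2s3y (-2.76), the IgA heavy chain Igha (-2.65, 0.588 against 3.23 units), Stk35 (-2.39), Zfp353-ps (-2.21), Kdm5d (-2.20) and Ferd3l (-2.11). They were followed by Cr2 (-2.09), carbonic anhydrase 2 (Car2, -2.08), Chil3 (-2.01), Tlcd1 (-2.00) and the erythroid gene Hemgn (-1.97). The values of Eif2s3y, Stk35, Ferd3l and Hemgn are lower bounds of the size. All 24 passed without any 1 of the 8 arrays, 14 with no floor and 17 with no floor and the probe sets held. None of the other probe sets of Usp50 (0 of 1) and Efcab1 (0 of 2) had the same direction.

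Of 17 B1a cell genes, 12 were higher in B1a cells and none lower (median 0.663, adjusted p = 2.24e-12, adjusted p = 0.00108 with an estimated correlation), among them Plscr1 (1.65), Zbtb32 (1.57) and the aryl hydrocarbon receptor Ahr (0.95). Of 11 follicular genes, 6 were lower and 1 higher (median -0.23, adjusted p = 0.00507, adjusted p = 0.049 with an estimated correlation), with Fcer2a at -1.89, Cd55 at -0.52 and Bach2 at -0.37. Immediate early genes were higher (13 of 23, 2 lower, median 0.322, adjusted p = 5.62e-08, adjusted p = 0.049 with an estimated correlation), led by Jun (1.23), Ier3 (2.05), Atf3 (1.44) and Egr2 (0.64). Whether the culture of the B1a preparations raised these genes was not tested. Mitotic genes were lower (22 of 31, 1 higher, median -0.638, adjusted p = 4.84e-07, adjusted p = 0.0686 with an estimated correlation), as Mki67 (-0.89), survivin (Birc5, -0.78) and cyclin A2 (Ccna2, -0.75) show. Lower lists with adjusted p from 0.00234 to 0.04 were marginal zone (5 of 11), S phase (8 of 28), germinal centre (5 of 8), MHC class II (6 of 9) and B cell receptor genes (12 of 25, 4 higher), whose adjusted p with an estimated correlation was 0.0604, 0.333, 0.272, 0.278 and 0.351. They hold Cd1d1 (-1.06), Mybl1 (-1.64), H2-Ob (-0.38), Cd72 (-1.15) and Blnk (-0.71), and the inhibitory receptor Fcgr2b was higher (0.55). Glycolysis genes were higher (4 of 13, adjusted p = 0.00874, adjusted p = 0.141 with an estimated correlation), among them hexokinase Hk2 (0.86). Of lists that did not pass, cell cycle regulators included cyclin Ccnd2 (1.01), the inhibitors Cdkn2d (1.33) and Cdkn1b (-0.52), and plasma cell genes included Prdm1 (1.86) and Jchain (-1.38). Markers of other cells differed as well. Macrophage markers were higher in B6_B1a (10 of 16, 2 lower, median 0.577, adjusted p = 0.000289, adjusted p = 0.333 with an estimated correlation). Mast cell markers were higher (7 of 9, median 1.16, adjusted p = 1.17e-06, adjusted p = 0.0338 with an estimated correlation), among them Hdc (1.53) and Cpa3 (1.37). NK cell markers were lower (5 of 9, median -1.01, adjusted p = 0.000107, adjusted p = 0.0511 with an estimated correlation), among them Klrd1 (-1.48). The other 20 lists did not pass (lowest adjusted p = 0.0867), and 11 of them differed in sign between median, mean and test. The count was lowest without B6_Bs 2 (3315) and highest without B6_Bs 1 (6416).

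**Figure D2:**
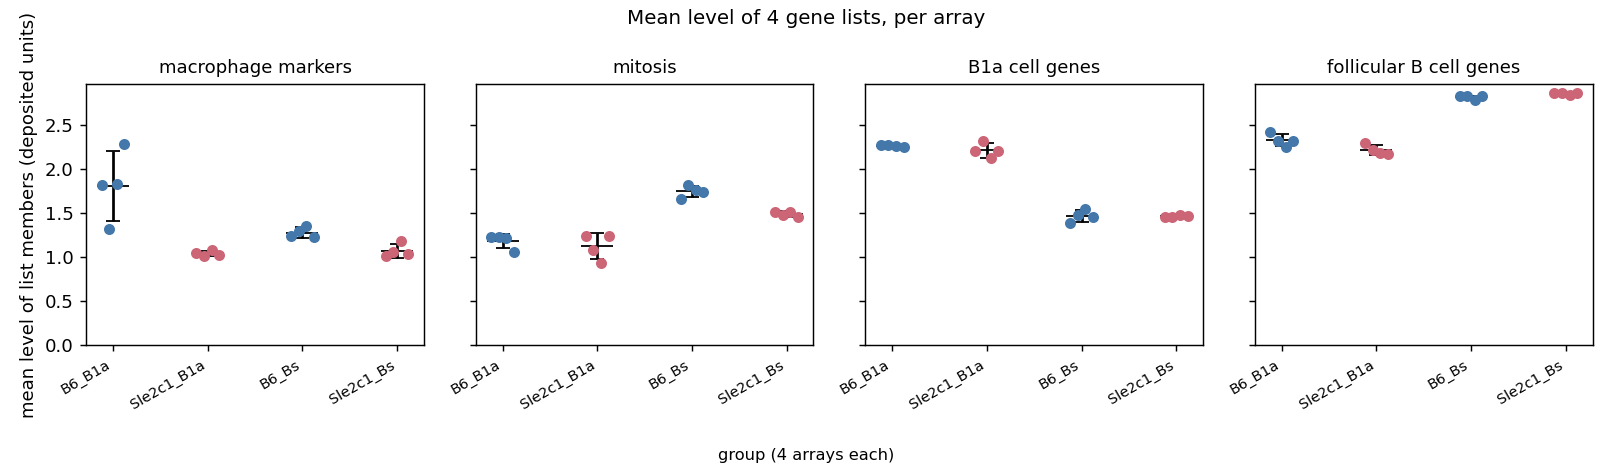
Mean level of macrophage markers, mitotic genes, B1a cell genes and follicular B cell genes on each array (y axis, units of the deposited score) by group (x axis), with each group's mean and SD (n = 4). Macrophage markers averaged 1.81 in B6_B1a and 1.04 to 1.28 in the other groups, and mitotic genes 1.75 in B6_Bs and 1.49 in Sle2c1_Bs.

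In Sle2c1 mice the comparison of cell types asks whether the reference difference holds with the segment. Il10 was higher in B1a cells by at least 2.16 units, Plscr1 by 1.75, Zbtb32 by at least 1.53 and Ahr by 1.08. Cr2 fell by 2.54, Fcer2a fell by 2.13 and Igha lay at the floor in B1a cells (-2.38, a lower bound of the size). The limma test called 2508 features higher and 3348 lower in B1a cells (1973 and 2183 named genes), with 8759 at an unadjusted p under 0.05 and 25.5% of features without overlap. Of the features past the test, 1465 were higher and 1898 lower in both strains, and 7 passed in opposite directions. By chance 226 and 410 would be shared were the tests independent, but they share the estimated spread of each feature. Across all genes the differences of the strains correlated with r = 0.818, and genes are not independent replicates.

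The largest higher differences were of Cep128 (at least 2.74), Usp50 (at least 2.74), Cxcl2 (2.70), Snd1 (at least 2.70), Efcab1 (at least 2.67), Syne2 (at least 2.58), Xist (2.55), Lmo7 (2.46), Csnk1e (at least 2.42), Igfals (at least 2.37), Fzd6 (2.36) and the magnesium transporter Slc41a1 (at least 2.36). The largest lower ones were of Rps27 (-3.14), Gm15511 (-2.67), Eif2s3y (-2.61), Cr2, Igha, the costimulatory ligand Icosl (-2.35), Ccdc150 (-2.24), the Ras exchange factor Rasgrp3 (-2.23), Ferd3l (-2.20), Stk35 (-2.18), Fcer2a and Dact3 (-2.11). Those of Rps27, Igha and Dact3 are lower bounds of the size. All 24 passed without any 1 of the 8 arrays, 18 with no floor and 22 with no floor and the probe sets held. The other probe sets of Cep128 (0 of 3), Snd1 (0 of 1), Icosl (0 of 1) and Dact3 (0 of 2) did not have the same direction. Of 17 B1a cell genes 10 were higher and 1 lower (median 0.715, adjusted p = 1.09e-08, adjusted p = 0.00539 with an estimated correlation), and 6 of 11 follicular genes were lower (median -0.173, adjusted p = 0.000803, adjusted p = 0.0248 with an estimated correlation). Mitotic genes were lower (17 of 31, 3 higher, median -0.498, adjusted p = 0.00409, adjusted p = 0.317 with an estimated correlation), with Cdk1 at -0.86 and Bub1b at -0.63, and the GTPase activator Racgap1 higher by 0.52. Marginal zone (5 of 11 lower), MHC class II (6 of 9 lower) and B cell receptor genes (16 of 25 lower, 3 higher) had adjusted p of 0.000803, 0.000864 and 0.00409, and 0.0552, 0.244 and 0.317 with an estimated correlation. Immediate early genes (9 of 23 higher, 1 lower, median 0.136, adjusted p = 0.000864) and glycolysis genes (6 of 13 higher, 1 lower, adjusted p = 0.0392) were higher, each with an adjusted p of 0.244 with an estimated correlation, and Myc rose by 0.92. NK cell markers were lower (5 of 9, median -0.498, adjusted p = 0.00255, adjusted p = 0.165 with an estimated correlation) and mast cell markers higher (4 of 9, median 0.535, adjusted p = 0.000803, adjusted p = 0.101 with an estimated correlation). Macrophage markers did not pass in this strain (3 of 16 higher, 5 lower, adjusted p = 0.791), nor did the other 22 lists (lowest adjusted p = 0.0619), and plasma cell and ER stress lists differed in sign between median, mean and test.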

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

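The tests of dim-signal loss, of an upward shift of dim values and of interaction splits that keep the Bs pairs apart were chosen only after the results they bear on were seen.

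The number of features whose strain effect differed between B1a and Bs cells, 98, drew attention because the interaction itself was tested. Of 100 splits of the arrays, 3 gave as many features, the real one included. These splits mix the strains within both cell types, so that they undo every strain effect and not the interaction alone. They therefore cannot exclude chance for the interaction. Another split gave 312, which points to a structure of the samples beyond the groups. Of the 26 splits that part all 4 pairs of Bs arrays, the real one alone gave as many, and the highest other gave 4. With the replicate block within each cell type the interaction passed for 45 features, 34 of them shared with the 98. The interaction passed for 1700073E17Rik (1.45), Olfr480 (1.421), Sall3 (1.36), Limch1 (1.324) and Tdpoz1 (1.235). In the other direction it passed for Timd4 (-1.916), Adamts4 (-1.446), Faah (-1.304), Ackr3 (-1.302) and Lpl (-1.302). Without any 1 of 10, 7 and 2 of the 16 arrays Timd4, Faah and Lpl did not pass (adjusted p 0.0543 to 0.0938, 0.0512 to 0.0681 and 0.0506 to 0.0527), and the count lay between 48 without B6_Bs 4 and 183 without Sle2c1_B1a 1.

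For the strain comparison in B1a, 1 of 35 splits gave 768 features or more, the real one, and the highest other gave 316. This argues against chance without excluding it, since 1 of 35 is the smallest share these splits can give. In Bs, 3 of 35 splits gave 35 features or more, and 1 that put B6_Bs 1, 2 and 4 with Sle2c1_Bs 4 gave 166. Chance can therefore not be excluded in Bs, and that split points to a structure of the Bs samples. Among the 8 splits that part all 4 pairs of equal replicate number, as the real one does, the highest other gave 1. With replicate number as a block 30 features passed, with a block within each cell type 25, and with the block in the 8 Bs arrays alone 1. For the cell types, 1 of 35 splits gave as many features in each strain, the real one (4833 in B6, highest other 845, and 5856 in Sle2c1, highest other 201). Chance is argued against here too, again at the smallest share that 35 splits can give.

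Macrophage markers were lower in Sle2c1_B1a than in B6_B1a with a median of -0.775. Loss of dim signal on the Sle2c1_B1a arrays is argued against by 10000 random lists matched on level, of which 0% had a median as low (lowest -0.277). Fewer macrophages left in the Sle2c1_B1a preparations may explain the difference. Adherence and CD5 selection were steps against such cells, but the labels put the B1a preparations at 80% B220int CD5+ cells, which leaves room for others. In a second macrophage list that shares no gene with the first, 23 of 29 genes were lower and 4 passed (Ccl9, Cxcl13, Lyz1, Saa3). The median was -0.15, between the bounds set beforehand. Msr1 (-0.99), Cd5l (-0.86) and Fcna (-0.64) fell to the floor in Sle2c1_B1a without passing. Fcgr4 (0.455) and Ccr2 (0.365) were higher without passing. The abundant Tyrobp (2.93 and 2.92 units), Ctsb (3.05 and 3.04) and Ccl6 (difference 0.07) hardly differed. Fewer macrophages and a strain effect on the genes themselves cannot be told apart here, because the second list's median decides for neither.

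Of the 439 features higher in Sle2c1_B1a, 382 had at least 1 of the 8 B1a arrays at the floor, and 131 had all B6_B1a arrays there. The median strain difference over all other features in the range of levels of these 382 was 0.0525. This cannot decide on an upward shift of dim values on these arrays, because values raised to the floor hold that median down. Array medians were 0.87 to 1.09 in Sle2c1_B1a and 0.79 to 0.89 in B6_B1a, so that such a shift stays open. Signal of single probe sets may account for part of the rise. Of 106 other probe sets of these genes 70.8% differed in the same direction, but by a median of 0.085 where the genes differed by 0.964. This share lay between the bounds set beforehand, so that such signal and a change of the transcripts cannot be told apart.

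Single arrays lay far from the other 3 of their group in 3 of 70 groups of values tested, where chance gives about 5%. They were Yipf1 on Sle2c1_Bs 4 (0.97 units), the share of probe sets at the lowest value on B6_B1a 3 (27.63%) and the mean level of mast cell markers on Sle2c1_Bs 3 (0.74 units). Outside the main measurement, the Dap control probe set averaged 1.62 units over the 8 B1a arrays (1.28 to 2.40) and lay at the floor on all 8 Bs arrays.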

How the results depend on the processing

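Other floors, no floor, both with probe sets held, leaving groups at the floor out of the spread, blocks within a cell type or in the Bs arrays alone, leaving out 3 arrays, testing only features above the floor, and other windows around Cdkn2c at an adjusted p under 0.10 were chosen only after the data were seen. Planned fold thresholds and pseudocounts were not run, because the scale of the score is unknown. Except where a value follows, each count stayed within 1.5 times its reported value under the alternatives run, and the cause of a change was not tested unless given. A like count did not mean like calls: with no floor, 4 of 29 in Bs and 8 of 88 for the interaction were shared with the reported calls, and with a floor at 1, 40 of 93 for the interaction and 14 of 26 in Bs. The strain count in B1a (768) was 1231 with every probe set, 371 with only the 8 arrays compared, 1233 with array weights, 1272 at an adjusted p under 0.10, 438 with no floor (455 with the probe sets held), 454 with floored groups out of the spread. It was 50 among features above the floor on every array. In Bs (35) it was 14 after quantile normalization, 17 after median centring, 387 with array weights, 23 with a floor at 0, 1 with the replicate block in the Bs arrays alone, and 59 without the 3 arrays in doubt. It was 0 by limma among the 11892 features above the floor (286 at an unadjusted p under 0.05). The interaction (98) gave 162 with every probe set, 45 after median centring, 10 with trend and robust, 314 with array weights, 160 at an adjusted p under 0.10, 23 with floored groups out of the spread, and 45 with the block within each cell type. It gave 0 by limma among the 8943 features above the floor (479 at an unadjusted p under 0.05). Cell types gave 10442 in B6 with array weights and 3611 in Sle2c1 among features above the floor. Leaving out each array in turn gave 522 to 1101 for strain in B1a, 22 (without B6_Bs 2) to 63 (without B6_Bs 3) in Bs, 48 (without B6_Bs 4) to 183 (without Sle2c1_B1a 1) for the interaction, 3315 to 6416 for cell types in B6 and 4348 to 6473 in Sle2c1. Cdkn2c differed by strain by -0.2125 in B1a and -0.415 in Bs with a floor at 1, where B6 values lie nearer to the floor, by -3.475 and -4.82 with no floor, and by -0.8937 in Bs with the block in the Bs arrays alone, none past the threshold (adjusted p 0.0602 to 1, over all alternatives 2.01e-05 to 1). Near Cdkn2c in Bs, Fisher's exact p at an adjusted p under 0.10 was 0.104, 0.02 and 0.00928 with 25, 50 and 100 genes on either side. Signs reversed with the mean of probe sets for Rrm2 (0.7633 in B6, 0.9562 in Sle2c1) and Cd247 (0.06688, cell type in B6). Where the floor changed, another probe set could have the highest mean and stand for the gene. This gave opposite signs with a floor at 0 for Gcsam (1.032, cell type in Sle2c1) and with no floor for Uty (-4.32, strain in B1a), Zfp518b (-0.835, strain in Bs), Efcab1 (-3.712 in B6, -1.395 in Sle2c1), Cep128 (-1.478, Sle2c1) and Snd1 (-0.025, Sle2c1). With the probe sets held, none of these reversed, and the interaction of Apoe did with no floor either way (0.145). Of 50 list results past the preset correlation, 7 passed with an estimated one, 28 by fry (which tests a list by itself), 48 with either block and 45 without the 3 arrays, and 0 changed the sign of the median after quantile normalization or median centring. The floor limits what can be seen, since 22.8% to 35.6% of each array's probe sets carry no level.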

Other observations

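The tests of sex as the whole cause, of separate labelling runs and of single probe sets for the cell types were chosen only after the results were seen. B1a and Bs arrays differed in 4833 features in B6 and 5856 in Sle2c1, while Xist, Eif2s3y and Kdm5d parted them too. The share of genes on X and Y past the test was at most 0.955 times that on autosomes (26.3% against 27.5% in Sle2c1, 18.7% against 22.4% in B6). This share cannot decide on sex of the mice as a cause, because an effect of sex need not lie on X and Y. Sex, as far as Xist, Eif2s3y and Kdm5d tell it, and cell type cannot be told apart. Signal of single probe sets as the whole cause is argued against by 2695 of 3551 other probe sets (75.9%) of the genes past the test in B6 that differed in the same direction. They did so by a median of 0.2 where the genes differed by 0.385, so that a part of the size stays open. Labelling or hybridisation in separate runs may have added to the difference, since the bioB control differed (3.33 ± 0.137 against 3.66 ± 0.211, exact p = 0.00404, 8 arrays each) and cre did not pass (exact p = 0.211). The Dap control goes with separate processing as well, at 1.28 to 2.40 units on all 8 B1a arrays and at the floor on all 8 Bs arrays. Because no label gives a run and Dap follows the cell types, runs and cell types cannot be told apart. The same holds for the 2 h of culture in 10% serum, which the labels give for the B1a preparations alone.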
